A study of Mus musculus with 4 samples.

How the data were processed

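Open chromatin was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, in stem cells sorted from crypts of mice carrying an EGFP reporter at the Lgr5 locus. Per the labels, the mice were 6 to 12 weeks old, 50000 cells were lysed per library, and the transposed DNA was amplified for 10 PCR cycles. The 4 libraries form 2 groups of 2: small-intestinal stem cells (SISC), sorted as Lgr5-EGFP positive and CD24 negative, and large-intestinal stem cells (LISC), sorted as Lgr5-EGFP positive with no CD24 gate named. Small-intestinal tissue came from stretches near the pylorus and near the cecum, and large-intestinal tissue from the whole length down to the rectum. Nothing in the labels says whether the libraries of a group came from separate animals, so the spread between them, which the SDs measure, may be partly technical; p-values are over genes or regions of these libraries and not over libraries. Y-chromosome regions were called in replicate 1 and not in replicate 2 of each group, so the replicates did not differ by technical spread alone.

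Per the submitters' processing notes, cutadapt 3.4, Bowtie2 2.3.4.1, Picard, MACS2 2.2.7.1 and bedtools were used with the mm10 build. The notes give no order or settings, and whether reads were shifted for the Tn5 insertion site, how duplicates were treated and which calling threshold was set are not given in the sources used here. The deposited values are MACS2 peak lists, 1 per library, since the peak names in each list carry a single library's name. In each list the authors deposited a fold enrichment (a ratio) at the peak summit over the local background of that library. The −log10 p and −log10 q of each peak are likewise the authors' values, and the deposited score column is 10 times the −log10 q, rounded down, in nearly every peak. These values depend on the depth of their own library and were used in the group comparisons only to rank or filter peaks within a list. The closing section also sets X-chromosome against autosomal medians within each library and compares those ratios, and applies 1 −log10 q minimum to both replicate 1 libraries. Read counts were not used here, so the depth of each library is unknown, and a region missing from a list was not called rather than shown to be closed.

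Peaks of all 4 lists that overlapped by at least 1 bp were merged into regions, and a library was taken to have a region when at least 1 of its peaks lay in it. Regions called in both libraries of 1 group and in neither of the other are termed SISC-only and LISC-only. With 2 libraries against 2 there are 3 splits of the libraries, so no exact test over libraries can reach 0.05; the smallest p it allows is 1 in 3. The counts were therefore set beside those of the other 2 splits. List similarity was the base-pair Jaccard index, shared over covered bases. Genes came from a RefSeq table of the GRCm38.p6 assembly, the same coordinates as mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table carries no strand, so the transcription start planned for the promoter and gene assignments was replaced by the nearer of the gene's 2 annotated ends, called a gene end here. A region was near a gene end within 1 kb and was given to the gene with the nearest end within 100 kb. A gene leaned to the group with more group-only regions.

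The 21 gene lists, the tests and the rule for named genes were fixed before the data were examined. Each list was compared with all other leaning genes by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the 21 lists and a threshold of 0.05. Of 342 distinct list genes, 340 were in the gene table, and Prac1 and Pla2g2a were not matched as protein-coding genes. Named were the sort markers Lgr5 and Cd24a, up to 4 members per list with the most group-only regions in the direction the list leaned, the 10 genes per direction with the most net regions, and the 5 group-only regions per direction with the highest mean within-list percentile of −log10 q. Some items this rule selects are not reported here. Other genes named below were chosen after their values were seen: members of the lists with a gene end in 1 group only, and genes of the closing section. Shares carry exact (Clopper-Pearson) 95% intervals, which treat regions as independent and describe these 4 libraries only. Direction was also shuffled 1000 times among group-only regions within each chromosome, a check added after the counts were seen.

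Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures from matplotlib 3.10.9; merging was checked against bedtools 2.31.1. The list test was tested on simulated data over the 8327 genes with group-only regions. A planted list of 20 such genes was found in 70% of simulations when each of its regions had an 80% chance of being SISC-only and in 99% at 90%; for a list of 10 such genes these shares were 25% and 61%. The fixed lists held 3 to 20 leaning genes (median 9), so most had less power than the simulated list of 20. A list with 3 leaning genes was too short to pass at any split. The simulation also drew the direction of each region independently and picked list genes at random. Neighbouring regions in the data often shared direction and some lists hold adjacent genes, so the simulated shares need not hold for the fixed lists. Alternatives were a −log10 q of at least 5, equal list lengths, 50% cover of a region, windows of 100 bp on each side of the summits, stricter presence, autosomes only, regions of at most 2000 bp, other gene-end windows and distances, distal regions only, matched random lists, a replicate block and leaving out each library. The planned comparison of 28 motifs was not run, because no genome sequence was used here.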

Results

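Accessible chromatin was profiled in Lgr5-positive stem cells of the mouse small intestine (SISC) and large intestine (LISC), with 2 libraries each. Lgr5 is a Wnt-responsive receptor that marks the crypt base stem cells. The peak lists held 83443 and 93220 peaks for SISC replicates 1 and 2 and 91313 and 88739 for LISC replicates 1 and 2, covering 49.9, 63.3, 55.5 and 58.3 Mb. Read depth is unknown, and the authors' median fold enrichment per peak was 5.76, 4.92, 5.56 and 4.38 in the same order. All coordinates are mm10.

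The series compares the chromatin of both stem cell types. Olfm4, a secreted glycoprotein known as a marker of small-intestinal stem cells, had 14 regions called in both SISC libraries and in no LISC library. Gata4, a transcription factor of the proximal small intestine, had 9 such regions. Ikzf2, an Ikaros-family transcription factor, had 16 regions called only in LISC against 0 only in SISC, and Car1, a carbonic anhydrase of the colonic epithelium, had 8 against 0. Genome-wide, 9555 regions were SISC-only and 12191 were LISC-only, out of 119965 regions in all. Another 57829 regions (48.2%) were called in all 4 libraries.

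The 21746 group-only regions exceeded those of the other 2 splits of the libraries, which gave 1924 (replicates 1 against replicates 2) and 1725 (crossed), or 11.3 and 12.6 times fewer. The Jaccard index was 0.719 ± 0.0265 within groups (SD over 2 pairs; 0.701 for SISC, 0.738 for LISC) and 0.586 ± 0.0102 between groups (SD over 4 pairs), a difference of 0.134. With 3 splits no exact test over libraries could pass 0.05. LISC-only regions were also the more numerous at equal list lengths (11124 against 9662). With a lone LISC library they led SISC-only regions without LISC replicate 1 (18345 against 12824) and without LISC replicate 2 (17904 against 12088). With a lone SISC library they led without SISC replicate 2 (16228 against 12337), but not without SISC replicate 1 (13422 against 20577). As a lone library then defines 1 group, leaving out libraries does not settle which side has more.

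**Figure D1:**
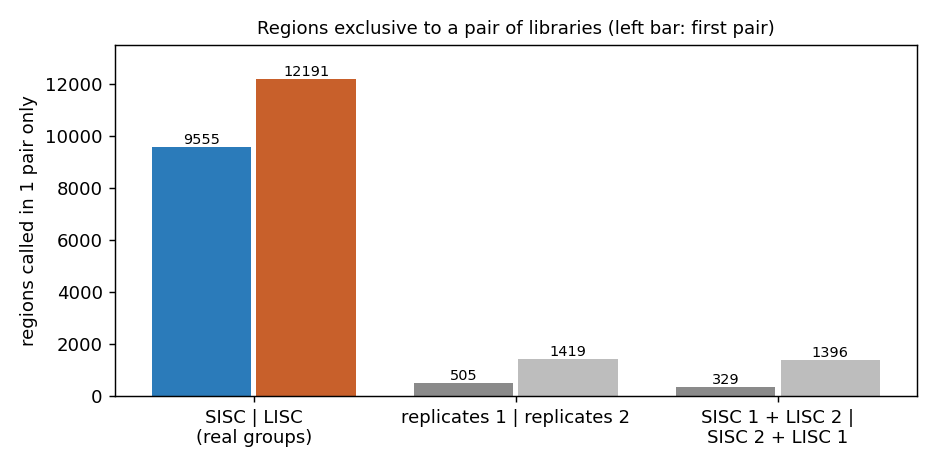
Bars give the number of regions (y axis) called in both libraries of 1 pair and in neither of the other, for the 3 ways of pairing the 4 libraries. The real groups gave 9555 SISC-only and 12191 LISC-only regions, and no pair in the other 2 splits gave more than 1419.

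The sort markers themselves were accessible in both tissues. Lgr5 (chromosome 10, 115450314 to 115587780) had 11 regions, of which 6 were called in all 4 libraries, 1 was SISC-only and none was LISC-only, and a gene end of Lgr5 carried a region in every library. Cd24a, the surface antigen used to exclude cells from the SISC gate, had 17 regions, with 8 in all 4 libraries, 3 SISC-only and 2 LISC-only.

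By nearest gene end, genes with the most SISC-only regions were led by Olfm4 (chromosome 14, 80000302 to 80023141), whose 21 regions included only 2 called in all 4 libraries. The region over its lower end (79999824 to 80001108) had a −log10 q of 231 in SISC replicate 1 and 156 in SISC replicate 2. Ccbe1 and Rbm19 followed with 11 SISC-only regions each, then Slco3a1 with 10, Cpvl, Gata4 and Neto1 with 9 each, and Itga9 and Myrfl with 8 each; none of these had a LISC-only region. Prdm16, a zinc-finger transcriptional regulator, had 9 SISC-only regions and 1 LISC-only region. The order depended on the assignment. When a region inside a gene body went to that gene, Slco3a1 had 16 SISC-only regions and 1 LISC-only region, Prdm16 15 and 1, and Olfm4 14 and 0. By the same assignment Dym had 17 LISC-only regions and Ikzf2 16, with 0 SISC-only regions at either. On the LISC side, Ikzf2 (chromosome 1, 69531207 to 69687351) had 16 LISC-only regions and no SISC-only region among its 22 regions. Other genes with many LISC-only regions were Ldlrad3 with 13 and 0, Trabd2b with 14 and 1, Dym and Palmd with 12 and 0, Hs3st3b1 and Lrriq3 with 11 and 0, and Cmah and Cpne8 with 10 and 0. All genes with 5 or more net group-only regions numbered 80 on the SISC side and 183 on the LISC side. No gene reached 5 under the other 2 splits, whose group-only regions are far fewer. Shuffled directions gave a median of 14 and 55 such genes and at most 27 and 80, with at most 11 net SISC-only and 16 net LISC-only regions at a gene, so that of the genes named here Olfm4 alone lay above every shuffle. Among the 41721 strongest peaks of each list the counts were 6 and 28. Without SISC replicate 1 the SISC count was 428, and the LISC count was 302 without SISC replicate 2, 365 without LISC replicate 1 and 358 without LISC replicate 2.

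**Figure D2:**
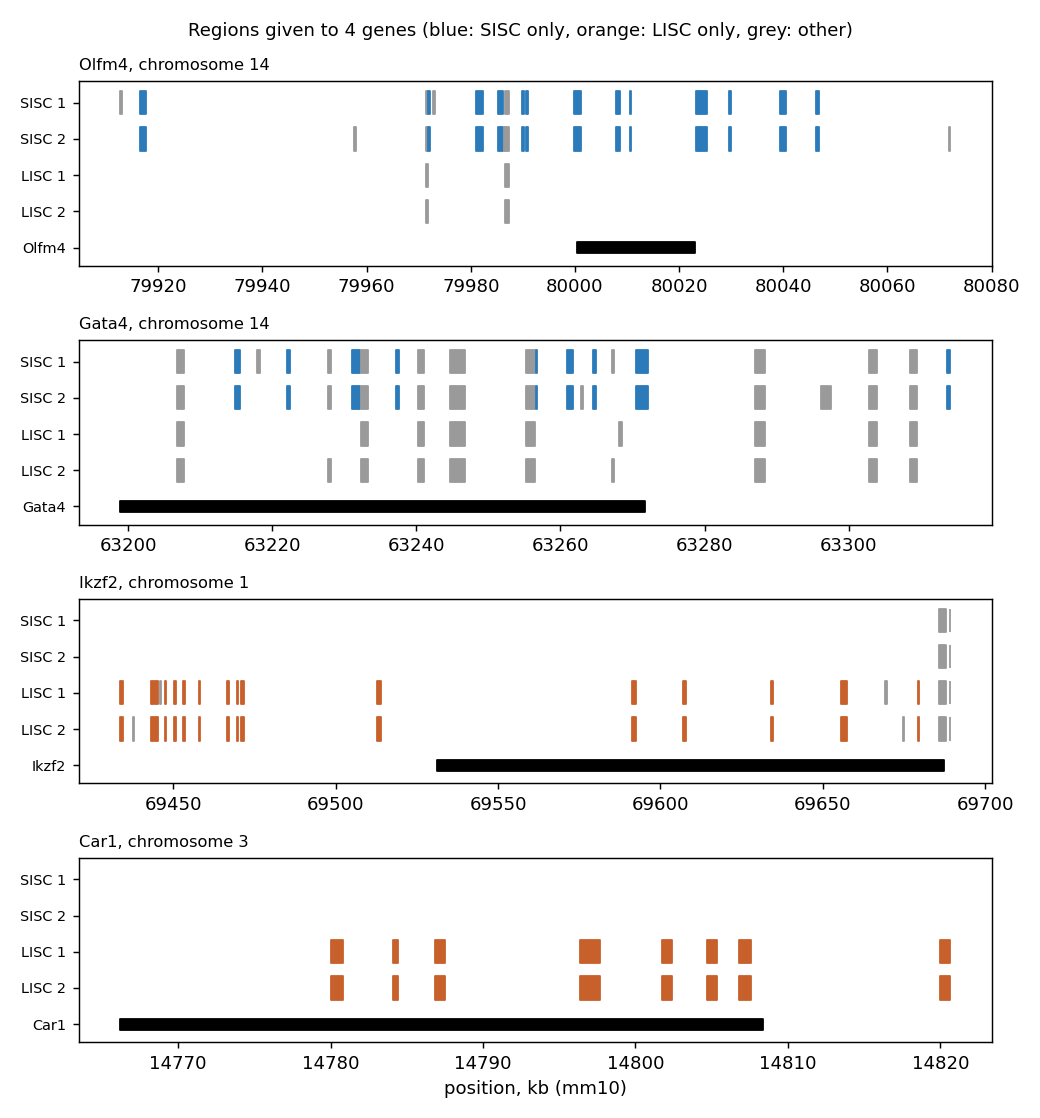
Each panel maps the regions given to Olfm4, Gata4, Ikzf2 or Car1 by library, with position in kb on the x axis, the 4 libraries as tracks and the gene body as a black bar; blue regions are SISC-only, orange LISC-only and grey all others. All 8 Car1 regions appear in both LISC tracks and in neither SISC track, while Olfm4 has 14 blue regions and Ikzf2 has 16 orange.

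The strongest group-only regions, by the authors' −log10 q ranked within each list, lay away from gene ends. For SISC the top region (chromosome 11, 117946535 to 117947433) lay 19.1 kb from an end of Socs3, an inhibitor of cytokine signalling, with a −log10 q of 271 in one SISC library and 337 in the other. The next 4 were nearest to Nrxn3, Filip1l, Ipo5 and Atp10a, between 100 and 523 kb from the gene end, inside the gene body for Nrxn3 and Filip1l. For LISC the top region (chromosome 2, 54236824 to 54237894) lay 152 kb from Rprm, and others were nearest to Pik3c3, Cdc73 and Tecrl, at 45.0 to 551 kb.

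Regions shared by all libraries lay near gene ends most often. Of regions called in all 4 libraries, 24.5% (95% interval 24.2 to 24.9) lay within 1 kb of a gene end, against 7.15% (6.64 to 7.68) of SISC-only and 3.76% (3.43 to 4.11) of LISC-only regions. The odds ratios against the shared regions were 0.237 (0.219 to 0.257) for SISC-only and 0.120 (0.109 to 0.132) for LISC-only. SISC-only regions lay near gene ends more often than LISC-only regions, with an odds ratio of 1.97 (1.75 to 2.23; Fisher exact p = 1.98e-28 over regions, which are not replicates). The median distance to the nearest gene end was 9.75 kb for shared, 17.9 kb for SISC-only and 30.8 kb for LISC-only regions, and median widths were 888, 457 and 484 bp.

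At the level of gene ends, 13594 of 21887 protein-coding genes carried a region in all 4 libraries and 7004 in none. A gene-end region in both SISC libraries and no LISC library was found for 301 genes, and the converse for 152, against 10 and 26 or 3 and 29 under the other splits. Among the fixed lists, the SISC-only genes were Olfm4, Gata4, the Hox genes Hoxc12 and Hoxd10, the absorptive genes Fabp1, Apoa4, Slc6a19 and Rbp2, the cytochromes P450 Cyp3a11 and Cyp2b10, the antimicrobial lectins Reg3a and Reg3b, the integrin gene Itgam and the neurofilament gene Nefl. The LISC-only genes were Car1, the chloride-bicarbonate exchanger gene Slc26a3, the epithelial sodium channel subunit gene Scnn1b, Hoxb3 and Tlr4. The Gata4 region (chromosome 14, 63270450 to 63272160) had a −log10 q of 28.9 and 58.6 in the SISC libraries, and the Car1 region (chromosome 3, 14806775 to 14807558) 35.0 and 24.6 in the LISC libraries. The SISC count was 544 without SISC replicate 1 and 464 when a peak had to cover 50% of a region; the LISC count was 250 without SISC replicate 2.

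Gene groups were compared by the number of members leaning to each tissue. Markers of the large-intestinal epithelium held 12 LISC-leaning and 2 SISC-leaning genes, among them Car1, Car2 with 7 LISC-only regions and no SISC-only region, and the forkhead gene Foxd2 with 6 and 1. Goblet and deep crypt secretory markers held 8 LISC-leaning and 1 SISC-leaning gene, with Kit at 3 LISC-only regions and Atoh1, the secretory lineage factor, at 2, neither with a SISC-only region; a CD24 gate was named for SISC alone. Proximal transcription factors stood at 6 SISC-leaning and 1 LISC-leaning gene, the latter being Gata6 with 11 LISC-only and 6 SISC-only regions. Of the SISC-leaning genes, Gata4 had 9 SISC-only regions and the others leaned by 1 region each. By the Fisher exact test these lists had p = 0.0132, 0.0395 and 0.0638 (adjusted 0.278, 0.415 and 0.447), beside 48.7% SISC-leaning among all leaning genes (3639 of SISC and 3827 of LISC). None of the 21 lists passed the threshold, 2 had an unadjusted p under 0.05, and matched random lists also gave 0 lists. The shortest lists could not have passed at any split.

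Library choice changed this count. Without SISC replicate 1 the SISC share of leaning genes was 25% for the large-intestinal list and 12.5% for the goblet list. With all libraries these shares were 14.3% and 11.1%. The test sets each list against all other leaning genes, and these changed too. SISC-only regions numbered 20577 without SISC replicate 1 and 9555 with all libraries, and LISC-only regions 13422 and 12191. Whether the lists leaned more strongly against the other genes is therefore not settled by these shares. Without SISC replicate 1, the large-intestinal list (adjusted exact p = 0.00846) and the goblet list (adjusted exact p = 0.0177) passed, and without LISC replicate 1 the large-intestinal list did (adjusted exact p = 0.028). Over all 16 alternatives the adjusted exact p ranged from 0.00846 to 0.601 for the large-intestinal list and from 0.0177 to 1 for the goblet list. By the net number of group-only regions, a statistic added after the data were seen, the large-intestinal list stood at -47 (adjusted permutation p = 0.0042 over 10000 random lists) and was the sole list past the threshold. The random genes were drawn independently of each other. In the list, Car1 and Car2 (net -8 and -7) are neighbours within 1 run of 17 LISC-only regions, so this p may be too small.

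**Figure D3:**
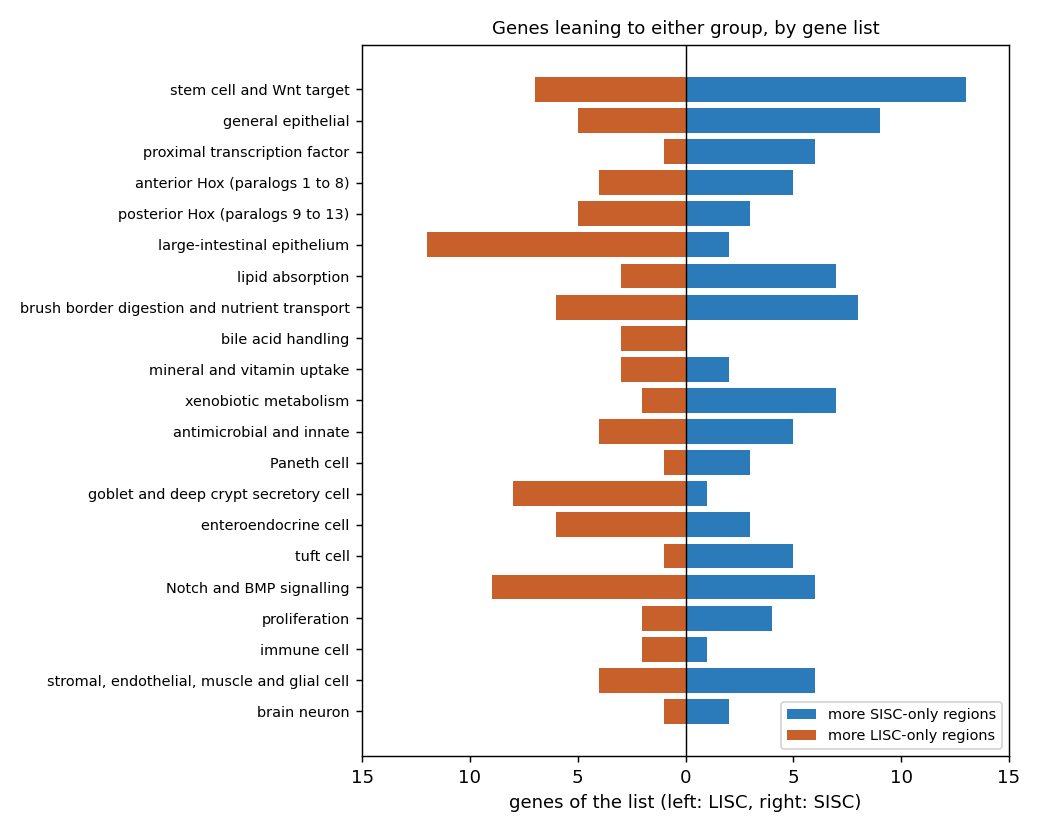
Bars give the number of genes (x axis) with more SISC-only regions (blue, right) or more LISC-only regions (orange, left) in each of the 21 fixed lists. The large-intestinal epithelium list shows 12 genes on the LISC side and 2 on the SISC side, and no list passed the adjusted threshold.

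Stem cell and Wnt target genes split 13 to 7 towards SISC (adjusted exact p = 0.631). Nkd1, a Wnt feedback inhibitor, had 5 SISC-only regions and Msi1 had 4, with no LISC-only region at either, and Cd44 had 5 of each kind; among the 41721 strongest peaks of each list Nkd1 stood at a net of -1. General epithelial genes split 9 to 5 (adjusted exact p = 0.679), and all 22 of their gene ends were called in all 4 libraries, as were all 18 of the proliferation list, which split 4 to 2 (adjusted exact p = 0.808). Notch and BMP signalling genes split 6 to 9 (adjusted exact p = 0.808), with Bmp2 at 4 LISC-only regions and 1 SISC-only region. Anterior Hox genes (paralogs 1 to 8) split 5 to 4 and posterior Hox genes (paralogs 9 to 13) 3 to 5, both with an adjusted p of 0.827. Hoxb9 had 4 LISC-only regions and no SISC-only region.

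Genes of absorption did not separate the tissues by this test, which the bile acid list, with 3 leaning genes, was too short to pass at any split. The lipid absorption list split 7 to 3 towards SISC (adjusted exact p = 0.647), with Mttp, which loads lipid onto apolipoprotein B, at 6 SISC-only regions and 0 LISC-only regions and Apob at 5 and 2. Brush border digestion and transport genes split 8 to 6 (adjusted exact p = 0.808), with Slc6a19 and Slc15a1 at 3 SISC-only regions each. Xenobiotic genes split 7 to 2 (adjusted exact p = 0.487), mineral and vitamin genes 2 to 3 (adjusted exact p = 1) and bile acid genes 0 to 3 (adjusted exact p = 0.657), the last with the ileal bile acid transporter gene Slc10a2 at 4 LISC-only regions and 1 SISC-only region. Antimicrobial and innate genes split 5 to 4 (adjusted exact p = 0.827), with Reg3b and Reg3g at 3 SISC-only regions each and Tlr4 at 6 LISC-only regions. In all, that list held 9 SISC-only and 12 LISC-only regions.

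Markers of other cells were also counted. Paneth cell genes split 3 to 1 (adjusted exact p = 0.762), enteroendocrine genes 3 to 6 (0.808) and tuft cell genes 5 to 1 (0.487), each as SISC to LISC with its adjusted exact p. Immune genes split 1 to 2 (adjusted exact p = 1), and 12 of the 19 had no gene-end region in any library. Stromal, endothelial, muscle and glial genes split 6 to 4 and brain neuron genes 2 to 1 (both adjusted exact p = 0.808). The Paneth, immune and brain neuron lists were too short to pass at any split. The gene ends of the stromal group were called at 11.5 ± 2.12 genes in SISC and 8 ± 2.83 in LISC (SD, n = 2 each).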

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

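All tests in this part were set before their own result was seen. Y-chromosome regions, none of which is SISC-only or LISC-only, were called in both replicate 1 libraries, 6 in SISC replicate 1 and 8 in LISC replicate 1, and in neither replicate 2 library. They stood out as a signal outside the group-only regions. Of the 8 regions, 6 were called in both replicate 1 libraries, and the strongest (Y, 1244859 to 1246026) had a −log10 q of 204 in SISC replicate 1 and 165 in LISC replicate 1. At Xist, the RNA gene transcribed from the inactive X (X, 103460373 to 103483233), 4 regions lay within 1 kb of a gene end. Those at 103481369 to 103482319 and 103483145 to 103483669 were called in both replicate 2 libraries and in neither replicate 1 library. The weaker one at 103484149 to 103484391 was called in SISC replicate 1 (−log10 q 13.3) as well as in both replicate 2 libraries, and the one at 103459894 to 103460374 in SISC replicate 2 alone. A region inside the gene, 103477265 to 103478001, was called in all 4 libraries with a −log10 q of 104 to 158.

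Weaker calling in the replicate 2 lists would lose comparable autosomal regions too, and only 5 of 36347 (0.0138%) that were at least as strong in both replicate 1 libraries were missing from both replicate 2 lists, which argues against it. A difference in the sex of the animals was then examined with 3 tests, of which the first 2 did not give what was predicted. The ratio of X to autosomal peaks was to be lower in both replicate 1 libraries, but replicate 1 over replicate 2 was 1.01 for the median fold and 1.05 for the median −log10 q; those predictions were unsound, since a second X chromosome is mostly inactive in females and adds little open chromatin, a point recognised only after both had missed. The third test asked for a region at an Xist gene end called in both replicate 2 libraries and in neither replicate 1 library, against regions called there in both replicate 1 libraries: 2 regions were of the first kind, with a lowest −log10 q of 25.7, and none of the second, which is consistent with males behind replicate 1 and females behind replicate 2, although the region shared with SISC replicate 1 does not separate them. Nothing in the labels gives sex, a mix of animals per library was not examined, and as the pattern falls across both groups alike it does not part SISC from LISC.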

How the results depend on the processing

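Chosen after the data were seen were the equal list length set by the shortest list, assignment by gene body, the net-region statistic and all values for genes with 5 or more net regions; the other alternatives were planned. Counts of SISC-only and LISC-only regions were 4670 and 5393 among the 41721 strongest peaks of each list, where fewer peaks entered, and genes with 5 or more net regions were then 6 and 28. The Jaccard difference was 0.104 with summit windows. Gene-end shares, in the order all 4, SISC-only and LISC-only, were 37.8%, 10.1% and 5.36% among the strongest peaks, 27.7%, 8.1% and 4.14% at 50% cover, 22.5%, 7.8% and 5.05% with summit windows, 22.0%, 4.81% and 2.29% at 500 bp, and 31.0%, 13.6% and 8.23% at 2500 bp, so their order did not change. At the length of the shortest list the first 2 shares were 25.1% and 7.78%. The SISC gene-end count was 464 at 50% cover. The net-region statistic gave 1 list, and Nkd1 turned to -1 among the strongest peaks; the cause was not tested.

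Leaving out 1 library at a time gave 12088 to 20577 SISC-only and 13422 to 18345 LISC-only regions, higher because a lone library then defines its group. The ranges were 0.111 to 0.157 for the Jaccard difference, 23.4% to 24.2% (all 4), 7.33% to 8.01% (SISC-only) and 4.02% to 4.63% (LISC-only) for gene-end shares, 337 to 544 and 177 to 250 for gene-end genes, 93 to 428 and 153 to 365 for genes with 5 or more net regions, and 0 to 2 lists. The replicate block, a region present in 1 group and absent in the other within both numbers, gave the same 9555 and 12191 regions by construction and a Jaccard difference of 0.128, and changed no call. Deviations of same-numbered libraries had a correlation of 0.0116 over regions. Their Jaccard index between groups (0.601 and 0.583, mean 0.592) was above that of differently numbered libraries (0.581 and 0.578, mean 0.580), and Y-chromosome and Xist regions went with the number in both groups, so whether the numbers pair the samples is open. Of 102 genes named by the rule, 41 kept their sign in all 12 alternatives and 19 took the other sign in at least 1; of the 26 above the highest net count of the other splits, 24 kept it. A net of 0 was counted as a sign that could be kept but not reversed. Hoxb3, at 0 throughout, is thus among the 41, while Cd44, at 0 with -1 to 2 in the alternatives, is not among the 19. Every motif alternative was not run, and 50% cover and stricter presence give no Jaccard index. Unknown depth limits all absences to calls not made.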

Other observations

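The shuffled counts of runs and genes and the test on secretory cells were chosen only after the result was seen. Group-only regions gathered into stretches of a single direction, here runs of at least 10 with gaps of at most 100 kb. The longest (chromosome 1, 69241810 to 69790575) held 31 LISC-only regions. Ikzf2 lay inside it, and the other nearest genes, Erbb4 and Spag16, lay beyond its ends. A run of 20 LISC-only regions spanned the interleukin-1 receptor cluster (chromosome 1, 40000997 to 40465981) with Il1r1, Il1r2, Il1rl1, Il1rl2 and Il18r1, and 17 spanned Car1 and Car2 (chromosome 3, 14780048 to 15076636). Mecom, a zinc-finger regulator, lay nearest to a run of 14 LISC-only regions. On the SISC side, runs held 16 regions at Prdm16, 15 at Ccbe1 and Pmaip1, 14 at Olfm4 over 130 kb and 13 at Gata4 and its neighbours. In all there were 68 runs, 24 SISC and 44 LISC, against at most 12 in 1000 shuffles of direction within chromosomes; the longest LISC run exceeded every shuffle (at most 21), whereas the longest SISC run of 16 did not (at most 17).

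Of gene ends outside the fixed lists, those called in both SISC libraries alone included Cps1, a mitochondrial enzyme of the urea cycle, Reg1, the iron hormone genes Hamp and Hamp2, and Ugt2b1. Those called in both LISC libraries alone included Il1rl1, Il18r1, Muc5b, the short-chain fatty acid receptor gene Ffar2 and Clca4a. Il1rl1 and Il18r1 have ends within 1 kb of each other (chromosome 1, 40465418 and 40465552), so 1 region can count for both. All genes of this paragraph were picked by eye and no group among them was tested.

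A hypothesis is that both tissues differ by domains rather than by single elements. Of 11580 neighbouring group-only regions 10 to 100 kb apart, 61.7% shared direction, against 49.5% to 52.6% in the shuffles (permutation p = 0.001, the smallest that 1000 shuffles can give). The share was 76.3% under 10 kb, 57.6% at 50 to 100 kb, 58.0% at 100 to 250 kb and 55.2% at 500 to 1000 kb. Shared direction was thus most frequent between the closest neighbours. The shuffles covered 10 to 100 kb only, so the shares at other distances have no such reference. Runs and shares count group-only regions alone, and regions called in all 4 libraries can lie between them. Dym had 12 of these beside 12 LISC-only regions and Prdm16 9 beside 9 SISC-only regions. Olfm4 had 2 beside 14 SISC-only and Ikzf2 2 beside 16 LISC-only regions. Neither the splitting of broad accessible stretches by the peak caller nor copy number was examined.

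That group-only regions lie away from gene ends could come from their being weaker or narrower. The odds ratio against shared regions was 0.17 without stratification, 0.367 within deciles of the −log10 q percentile (0.340 to 0.396) and 0.370 within deciles of width (0.345 to 0.397). Strength and width thus go with part of the difference, and neither accounts for all of it; both together were not tested. Regions called in 1 library only, which tissue does not define, lay near gene ends at 7.21% (6.90 to 7.54). This stood beside 7.15% of SISC-only and 3.76% of LISC-only regions, although the regions of 1 library were narrower (median 252 bp). A low share is thus not particular to regions that follow tissue, and whether tissue adds to it was not tested.

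Goblet markers stood on the LISC side, although their list did not pass the threshold (adjusted exact p = 0.415). A LISC gate with no CD24 exclusion may admit secretory cells, since CD24 is known on several secretory lineages. Such cells would bring enteroendocrine and tuft markers along, which together stood at 8 SISC-leaning and 7 LISC-leaning genes. By leaning genes the 2 kinds went opposite ways, with enteroendocrine genes at 3 SISC-leaning and 6 LISC-leaning and tuft genes at 5 and 1. By regions the tuft list was nearly balanced, at 5 SISC-only and 4 LISC-only, the latter all at Dclk1. The enteroendocrine list held 6 SISC-only and 10 LISC-only regions. The difference of the pooled genes from the goblet list was not decided (Fisher exact p = 0.0803). The gate and the tissue are confounded in this design and cannot be told apart for these genes.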
